A study of Homo sapiens with 12 samples.

How the data were processed

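The series applied MeRIP-seq, in which RNA fragments bearing N6-methyladenosine (m6A, a methyl mark on adenosines within mRNA) are pulled down with an antibody and sequenced beside an input library of the same RNA. The cells were H460, an established human large cell lung cancer line. Per the labels, 12 libraries form 4 groups of 3: input and immunoprecipitated (IP) libraries of untreated cells, and input and IP libraries of cells given 100 nM rapamycin for 24 h. Rapamycin inhibits the kinase complex mTORC1 and was used to induce autophagy. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library construction. Nothing in the labels says whether the replicates came from separate cultures.

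The data used here are 6 peak lists with 6 columns and no header line: chromosome, start, end, peak name, score and strand. Per the submitters' processing notes, the build was hg19 and HISAT2 2.0.4 was among the tools. The authors' deposited score is one value per peak. Its scale is not given in the sources used here. With a floor near 70 and many values at 3100 it may be a log-transformed p-value, which would rise with sequencing depth as well as with enrichment. The value 3100 is not a ceiling, since the highest score of a list lay between 3203.81 and 3233.06. It may stand in for p-values too small to be computed, so scores above it need not mark stronger peaks. The score was used to rank peaks within a list, higher values being ranked higher throughout, and as a common minimum. Medians per list are given as a description of each list and do not compare peak strength between lists. Peak names have the default form of the MACS caller, per the file contents; its version and settings, and which IP and input libraries went into each list, are not given in the sources used here. The authors' files hold a subset of the numbered calls, since peak numbers are not consecutive, and the lowest score lay between 70 and 70.08 in every list. No read count, coverage or library size was used here, so the depth behind each list is unknown and no counting interval or detection limit is given.

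The GEO record ties all 6 lists to untreated samples, 3 to inputs and 3 to IPs. The names given to 3 of the lists (A, B and C) carry con and the numbers 1, 2 and 3, and those of the other 3 (D, E and F) carry rapamycin and the numbers 4, 5 and 6. These are the words and numbers of the replicates in the sample titles of both arms, so the names disagree with the record for every list but A. Nothing inside the lists names a library. Before the data were examined it was decided that in this case no list would be assigned to a treatment arm from its name, length or values. The record was not followed either in treating the lists as input and IP pairs of untreated cells, so the arm and library of each list were left open. No comparison of rapamycin with untreated cells, and none of input with IP, was therefore made. The lists are called A to F, in the order of the samples they are tied to. Values are given per list, or as the range and median over lists, without a mean, an SD or a test over lists.

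An interval is one line of a list. Positions are hg19, written 1-based. Intervals of different lists were taken as overlapping when they shared at least 1 bp on the same strand. For each of the 15 pairs, the percentage of the shorter list's intervals overlapped by the other list and the Jaccard index (bp shared over bp in either) were computed. As a reference level, the longer list was moved by 100 kb and by 1 Mb in each direction and the median of the 4 percentages was taken. Moved intervals leave the transcribed segments, so this level is lower than that of unrelated peaks on the same transcripts. Overlapping intervals of all lists were joined into regions, and the number of lists holding each region was counted. The count expected of independent lists, foreseen beforehand, is not given, because it would have to be set over the union of called regions, which itself depends on the lists. Score agreement was measured by Spearman's rho across overlapping intervals, which are not independent replicates. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was checked on simulated lists of 2000 intervals, where 12 of 12 known values were recovered, and gave the counts of bedtools 2.31.1 in 3 of 3 pairs compared.

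The rule for named genes, fixed before the data were examined, called for the 10 genes with the highest median score percentile among those with a peak in all lists, members of preset gene lists (m6A machinery, core autophagy, mTORC1 and sestrins, and others), and the genes of the series title. The lists hold no gene names and the annotation at hand is of another build (GRCh38), so genes, transcript features, sequence motifs and the preset gene lists were not analysed here. The first part of the rule was carried over to regions, an adaptation made after the files were seen. Dense 1 Mb bins, width classes and peak numbers were likewise chosen for description after the files were seen.

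The alternatives fixed beforehand were a minimum score at the pooled median (260.435), every list cut to the 4530 best-scored intervals, a reciprocal overlap of at least 50%, merging of touching intervals, leaving out the Y chromosome, and leaving out each list in turn. Overlap without regard to strand was added after the data were seen.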

Results

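The series set out to find m6A changes in H460 lung cancer cells during rapamycin-induced autophagy. The data examined here were 6 lists of peak intervals from this series, called A to F, with 53502 intervals in all. Sequence motifs and transcript features were not analysed, so whether the intervals mark m6A was not checked. The GEO record ties every list to a sample of untreated cells: A, C and E to inputs 1, 2 and 3, and B, D and F to IPs 1, 2 and 3. A peak list of this kind rests on an IP and an input together, whereas the record ties each list to 1 library. The names under which A, B and C were deposited carry con and the numbers 1, 2 and 3, and those of D, E and F carry rapamycin and 4, 5 and 6, which are the replicates named in the sample titles of both arms. Because the record and these names disagree, the lists were not assigned to treatment arms and the effect of rapamycin was not tested. Each list was described on its own, and the lists were compared with one another by position. The sequencing depth behind the lists is unknown, and each value below is a single value per list without replicates.

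The first question was how much sequence each list covers. List A held 12040 intervals covering 9.84 Mb. List B was the longest, with 14908 intervals over 12.17 Mb, and list C held 12288 intervals over 11.65 Mb. List D held 4837 intervals over 5.40 Mb. List E was the shortest, with 4530 intervals over 4.84 Mb, and list F held 4899 intervals over 4.77 Mb. The longest list thus had more than 3 times the intervals of the shortest, and with 1 value per list no test of these differences was made. No interval overlapped another interval of its own list. In every list the strands were nearly balanced, with 50.02% to 51.7% of intervals on the plus strand.

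**Figure D1:**
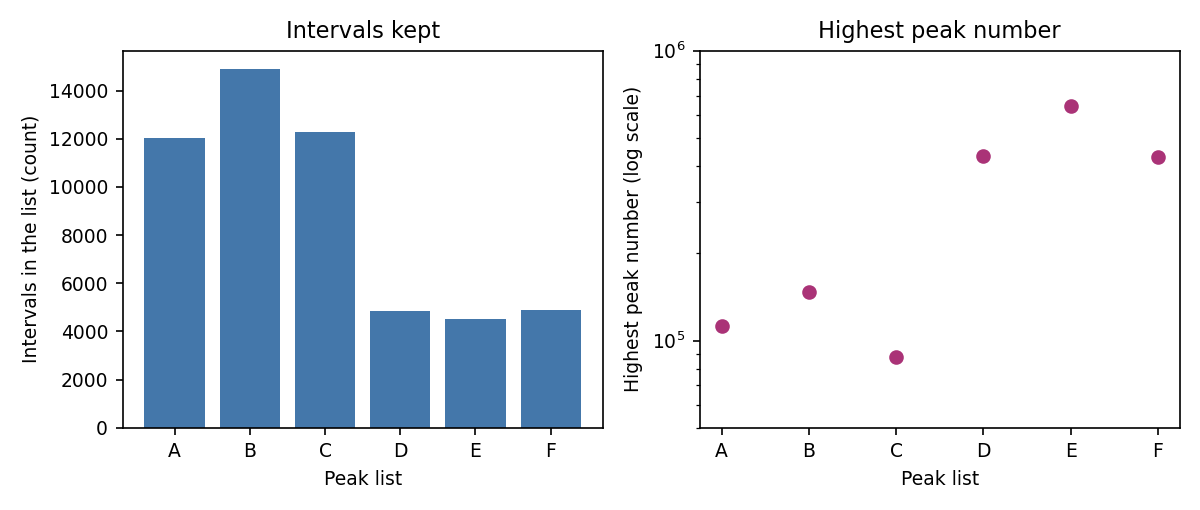
Number of intervals in each peak list (left, bars, linear axis from 0) and the highest peak number found in its peak names (right, points, log axis), for lists A to F. Lists A, B and C hold 12040 to 14908 intervals, and their highest peak numbers run from 87583 to 147164. Lists D, E and F hold 4530 to 4899 intervals, and theirs run from 429506 to 644965.

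Peak names carry a running number along the chromosomes, and within each list this number rose with position for 100% of neighbouring intervals. The highest number was 112236 in list A, 147164 in list B and 87583 in list C. It was 432460 in list D, 644965 in list E and 429506 in list F. Set against these numbers, the intervals kept amounted to 10.7% in A, 10.1% in B and 14.0% in C, and to 1.12% in D, 0.702% in E and 1.14% in F.

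The intervals spanned a wide range of widths, and the narrowest interval of a list was 1 to 15 bp wide. The median width was 452.5 bp in A, 526 bp in B, 631 bp in C, 819 bp in D, 829.5 bp in E and 624 bp in F. Intervals over 1000 bp made up 28.0% of list A, 27.9% of B, 33.9% of C, 42.1% of D, 41.5% of E and 34.3% of F. Those under 200 bp made up 29.0%, 23.4%, 21.8%, 14.2%, 13.5% and 20.2% of the lists in the same order. The widest interval of lists A, B and C was identical in position, on the minus strand of chromosome 11 from 62283374 to 62301546, 18173 bp long. In list D the widest interval lay on chromosome 14 from 105403680 to 105413077 (minus strand, 9398 bp), and in list F at 105403938 to 105414199 of the same chromosome and strand (10262 bp). List E had its widest interval on the plus strand of chromosome 15, from 43813522 to 43821706 (8185 bp).

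The median score was 242 in A, 371 in B and 347 in C, and 191 in D, 183 in E and 168 in F. Scores piled up at 3100: intervals at or above this value were 3.74% of A, 11.8% of B, 10.0% of C, 1.47% of D, 1.57% of E and 1.10% of F. Intervals at this value cannot be ranked against one another. The highest score of a list lay between 3203.81 and 3233.06. Whether a score above 3100 marks a stronger peak than 3100 is not known. The scale of the score is not known and it may rise with depth, so these values do not compare peak strength between lists. Wider intervals tended to score higher, with Spearman's rho between width and score from 0.23 in F to 0.43 in B across intervals of a list.

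**Figure D2:**
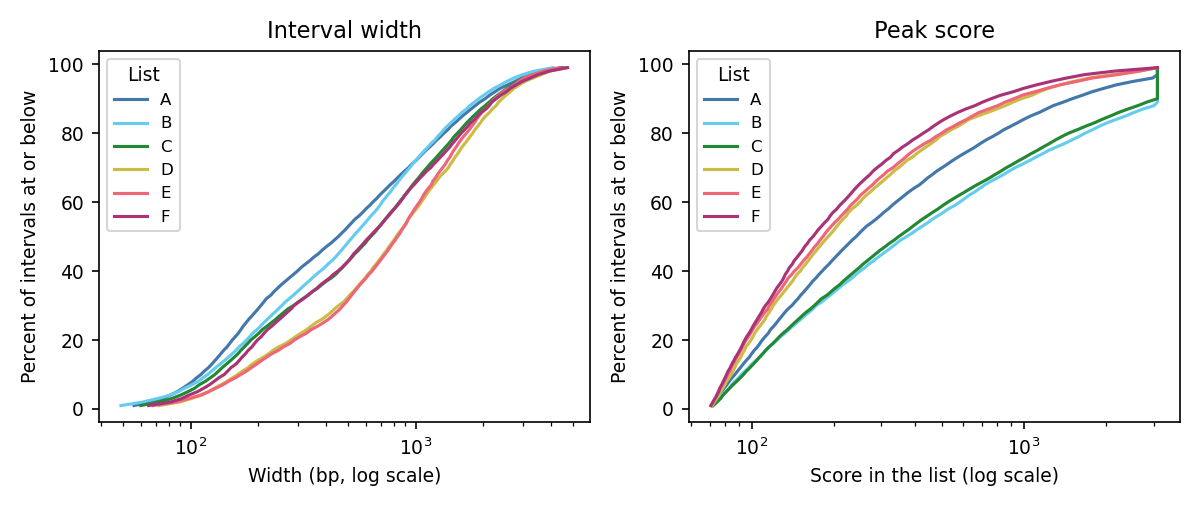
Cumulative percentage of intervals against interval width in bp (left, log axis) and against the authors' score (right, log axis), one line per list from its percentile 1 to 99. Lists D and E have the highest median widths (819 and 829.5 bp), and lists B and C have the most intervals at a score of 3100 or above.

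All 24 chromosomes were represented in every list, and the chromosomes took similar shares in each. Chromosome 1 held the most intervals, from 9.89% to 11.3% of a list. By the median over lists, chromosome 2 and the small chromosome 19 came next with near-equal shares, from 6.12% to 7.38% (median 6.55%) on chromosome 2 and from 5.87% to 7.02% (median 6.58%) on chromosome 19. Chromosome 2 held more than chromosome 19 in lists A and C, and fewer in the other lists. Chromosome 17 held 5.57% to 6.89%, and in list E it held more than either of them. Chromosome 13, which is longer than either 17 or 19, held only 1.47% to 1.86%, and chromosome 18 held 1.18% to 1.81%. Chromosome 21 had 0.728% to 1.09% of intervals.

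The second question was whether the lists cover the same places. Of the shorter list's intervals, 56.9% (D and F) to 86.3% (B and E) were overlapped by the other list, with a median of 77.5% over pairs. After one list had been moved along the chromosomes, this percentage was between 0.397% and 1.18%, a level that does not allow for both lists lying on the same transcripts. The percentage depends on list length, because a short list finds more partners in a long one. The Jaccard index, which counts unmatched sequence of both lists, was highest for B and C at 0.66, then A and C at 0.60 and A and B at 0.58. It was 0.47 for D and E, 0.44 for D and F and 0.43 for E and F. The remaining 9 pairs lay between 0.31 (B and F) and 0.39 (A and D). The index depends on length too, since it cannot exceed the smaller covered length over the larger. In these 9 pairs a list of 9.84 to 12.17 Mb was set against one of 4.77 to 5.4 Mb, which holds the index down. Scores of overlapping intervals were positively related in each pair, with Spearman's rho from 0.41 (A and D) to 0.71 (B and C).

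**Figure D3:**
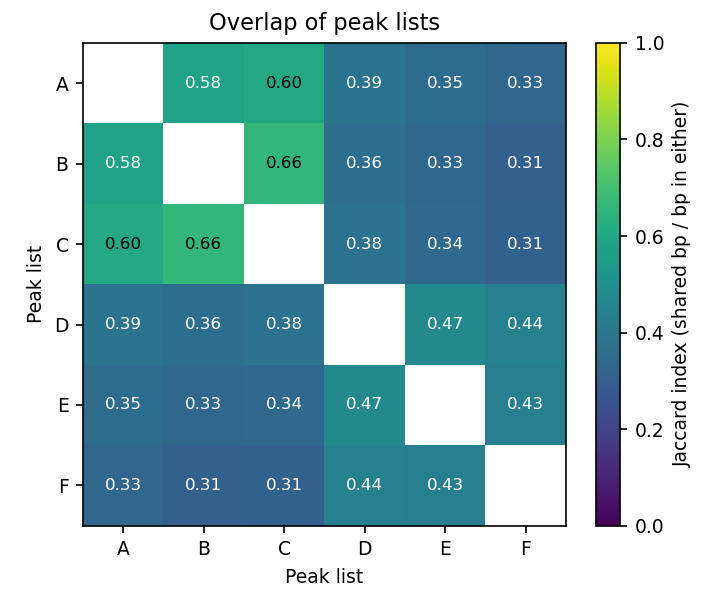
Jaccard index (bp shared over bp in either list, same strand) for each pair of lists A to F, as colour and number; the diagonal is left blank. The highest value is 0.66 for B and C and the lowest is 0.31. Pairs of lists with unequal covered length cannot reach 1, which lowers their values.

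Intervals of different lists often had exactly the same ends. Among overlapping intervals, both boundaries were equal in 54.6% (B and E) to 67.5% (A and F), and at least 1 boundary was equal in 94.0% to 97.0%. The scores of such intervals were nearly always different: outside the piled-up values, at most 2 of 4610 intervals with equal boundaries had equal scores in any pair (A and C).

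Joined over lists, the intervals formed 20742 regions. Of these, 1722 (8.30%) were held by all 6 lists, and 7655 (36.9%) occurred in 1 list. The numbers between were 4117 regions in 2 lists, 3646 in 3, 1967 in 4 and 1635 in 5. Regions found in all lists had a median width of 997.5 bp, and those found in 1 list had a median of 227 bp. The share of regions private to a list was 17.2% in A, 22.9% in B, 11.5% in C, 3.20% in D, 4.40% in E and 9.09% in F. Conversely, regions held by all lists made up 14.4% of A, 11.7% of B and 14.1% of C, and 35.7% of D, 38.2% of E and 35.2% of F. The number of regions in all 6 lists dropped to 572 when only intervals at or above the pooled median score were used, which leaves D, E and F with 1635 to 1860 intervals each.

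**Figure D4:**
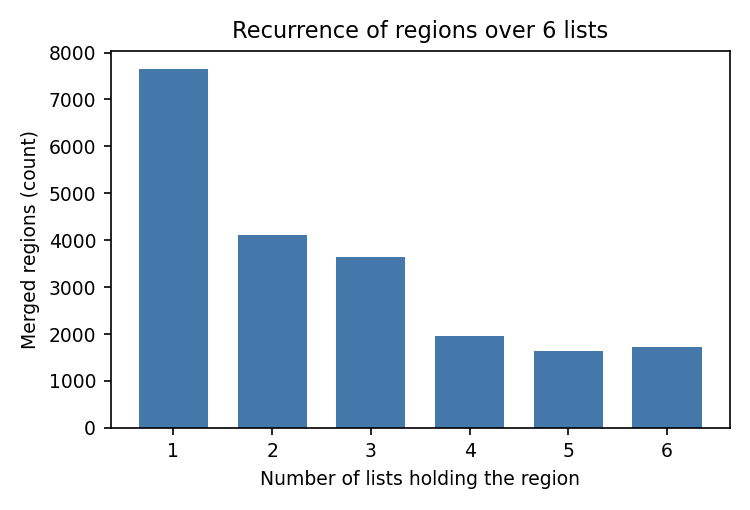
Number of merged regions (bars, linear axis from 0) by the number of lists that hold them. The count falls from 7655 regions in 1 list to 1635 in 5 lists, and 1722 regions are in all 6 lists.

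The regions with the highest scores throughout were at or above 3100 in each of the 6 lists. First by median score percentile (98.6) was chromosome 1 from 35654787 to 35654983, on the minus strand and 197 bp wide, with scores of 3204 in E and 3230 in F and 3100 in the other lists. Its first place rests on counting scores above 3100 as higher ranks, and whether they mark stronger peaks is not known. The next 22 regions were tied on their median and lowest score percentiles. The 9 named here are the first in chromosome order, and each stood at 3100 in every list. On chromosome 1 these were 171501482 to 171502100 and 181057638 to 181059979, both on the plus strand. On chromosome 2 they were 85553631 to 85554808 (minus), 99977611 to 99978283 (plus), 232326251 to 232326728 (minus) and 232328412 to 232328891 (minus). The others were chromosome 4 from 88903644 to 88904563 (plus), chromosome 5 from 17275317 to 17276954 (plus) and chromosome 7 from 148700154 to 148701301 (minus). Their widths ran from 478 bp to 2342 bp. The genes at these positions were not analysed here.

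Of the 1722 regions held by all lists, chromosome 1 held 190, chromosome 17 held 117 and chromosome 19 held 106. The share of a chromosome's regions held by all lists ran from 5.08% on chromosome 18 to 9.87% on chromosome 8, and was 9.68% on chromosome 17, 8.14% on chromosome 19 and 6.65% on chromosome 2. The 1 Mb bins with the most shared regions, 8 each, were chromosome 7 from 5000001 to 6000000 and chromosome 5 from 134000001 to 135000000. Bins with 7 lay at 16000001 to 17000000 on both chromosomes 1 and 19.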

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

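Merging touching intervals and leaving out the Y chromosome changed no interval count, covered length or median width beyond its limit. Ignoring strand (added after the data were seen) changed no overlap or region value beyond its limit. The limit was 1.5 times for counts, lengths and the Jaccard index and the 95% binomial interval for medians and percentages. For the overlap percentage, that binomial limit treats the intervals of a list as independent. It does not measure the spread of the median over pairs, which share lists. Overlap and region values were not computed after merging or without the Y chromosome, and values per list were not computed without strand. Merging joined no intervals, so it tests nothing. With scores at or above the pooled median, which removes weak intervals by construction, the lists kept 5718 (A), 8796 (B), 7071 (C), 1860 (D), 1671 (E) and 1635 (F) intervals. Their median widths became 672, 758.5, 903, 1078, 1042 and 877 bp in that order, and the covered length became 6.09 Mb in A, 2.55 in D, 2.21 in E and 2.03 in F. The median share of the shorter list overlapped was 77.46% as deposited. It was 78.64% at this minimum, 57.37% with every list cut to 4530 intervals, 73.33% with a reciprocal overlap of 50%, and 74.03% to 78.9% with each list left out in turn. Regions in all lists became 572 and regions in any list 11260 at the minimum score. At equal length they became 1155 and 9815, respectively. The fall from 1722 to 1155 lay just within the limit of 1.5 times. With each list left out in turn, regions in all remaining lists numbered 1747 to 2354 without B and without F, respectively. The median Jaccard index stayed between 0.2613 (minimum score) and 0.4346 (equal length), against 0.3794 as deposited. No paired analysis was possible because the lists could not be assigned to arms, whose replicate numbers (1 to 3 and 4 to 6) also differ. No Jaccard value was computed for reciprocal overlap, and the alternatives on genes, gene lists and arms were not run. Depth is unknown, so whether regions missing from D, E or F were undetected or absent cannot be read from the lists.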

Other observations

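The test on lowest scores, that on equal boundaries and those on peak numbers were chosen only after the result had been seen. Narrow regions recurred least. Of the regions up to 173 bp wide, 2.64% were held by all 6 lists and 55.5% by 1 list, whereas of those of 1029 bp or more, 16.2% were held by all lists and 13.0% by 1. Wider regions also offer more sequence to overlap, and joined regions grow with the number of lists. Of the 63 possible combinations of lists, the most frequent were B alone with 3387 regions, A, B and C with 2554, A alone with 2063 and all 6 with 1722.

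Interval counts, covered lengths and highest peak numbers fell into separate clusters, A, B and C against D, E and F. Median scores, shares at or above 3100 and shares under 200 bp or over 1000 bp formed no such clusters. Their values in A, B and C still did not overlap those in D, E and F. Only median widths interleaved. Interval counts were 12040, 14908 and 12288 in A, B and C and 4837, 4530 and 4899 in D, E and F. Highest peak numbers were 112236, 147164 and 87583 in the former and 432460, 644965 and 429506 in the latter. Median scores were 242, 371 and 347 against 191, 183 and 168, and intervals at or above 3100 made up 3.74%, 11.8% and 10.0% against 1.47%, 1.57% and 1.10%. On both of these values A lay nearer to D, E and F than to B or C. Intervals under 200 bp made up 29.0%, 23.4% and 21.8% against 14.2%, 13.5% and 20.2%, where C and F differed least. Median widths of C (631 bp) and F (624 bp) lay together, as did their shares of intervals over 1000 bp (33.9% and 34.3%). Among the 20 sets of exactly 3 lists, A, B and C, which are also the longest lists, held 2554 regions that were in no other list. The next set, A, B and F, held 151, and D, E and F held 59. Long lists form larger sets through their length alone, so these counts do not rank how closely the lists are related. The given names of D, E and F carry the word rapamycin and those of A, B and C carry con, but the record ties all to untreated samples, and none of these values can settle which is right. No biological explanation was tested, since no list could be assigned to an arm.

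For the difference in list length, a lowest score set differently per list is argued against by the lists' lowest scores, which differed by 0.08. With every list at the length of the shortest, A, B and C stayed most alike, with Jaccard indices of 0.54 (A and B), 0.55 (A and C) and 0.60 (B and C), followed by D and E with 0.47. F had 0.43 with D and 0.42 with E, above its 0.36, 0.37 and 0.37 with A, B and C. D and E came closer to A, B and C, with 0.39 (A and E) to 0.44 (C and D). The list with the highest index was kept by 6 of 6 lists (C for A and B, B for C, E for D, D for E and F), which argues only against length alone setting it. The cut kept the best-scored intervals, so A, B and C lost their low-scored intervals while D, E and F stayed nearly whole. Equal length was thus not an equal lowest score, and the higher indices among A, B and C may come partly from this cut. Recurrence followed score: in each of the 30 ordered pairs, intervals found in the other list had a higher median score percentile than those not found, by 21.0 points at the least and 41.2 at the most. The share found in at least 1 other list was 82.9% in A, 77.3% in B, 88.5% in C, 96.8% in D, 95.6% in E and 90.9% in F, and short lists have longer partners to be found in; sequencing depth, pull-down efficiency, background and treatment all stay open.

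Equal boundaries in different lists could arise if intervals were limited to a fixed set of boundaries, such as those of annotated exons, after peak calling. This stays open: the lowest share of overlapping intervals with both boundaries equal, 54.6%, is the pattern itself and no test of it, and the boundaries were not compared with exons. Intervals of a few bp (the narrowest of a list was 1 to 15 bp) could also arise in this way. If so, the widths, strand shares and overlaps given above describe the limited intervals and not the peaks as called. Derivation of several lists from the same scored calls is argued against by the scores, which were equal in at most 0.0434% of intervals with equal boundaries. Shared calls scored separately for each list would also have unequal scores, so the test cannot exclude them. A regular grid of positions is argued against by starts at whole multiples of 10, at most 10.7% in any list where 10% is even.

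The peak numbers offer a view of all numbered calls, with the intervals kept among them. Those kept were 10.1% to 14.0% of the numbers in A, B and C, and 0.702% to 1.14% in D, E and F. They were not subtracted, so the weights below do not describe the calls not kept by themselves. The share of numbered calls per chromosome was fitted, over the 22 autosomes and X, as a mixture of chromosome span (the furthest interval end in any list) and the distribution of the 20742 regions. The weight on span was 0.39 in A, 0.32 in B and 0.37 in C, with jackknife standard errors of 0.061, 0.079 and 0.055. It was 0.78 in D, 0.85 in E and 0.72 in F, with standard errors of 0.11, 0.095 and 0.11. Leaving out 1 chromosome moved it between 0.68 and 0.81 in D, 0.77 and 0.88 in E, and 0.63 and 0.75 in F. Some chromosomes lay outside both components, so no mixture of them can describe the calls fully. In D, chromosome 5 held 7.33% of calls (5.96% of span, 4.99% of regions) and chromosome 22 held 1.13% (1.69% and 2.21%). In A, chromosome 7 held 6.06% (5.24% and 4.95%). The weights are thus not fractions of calls from either source. In none of the 6 lists was the weight above 0.75 or below 0.25 by more than its standard error under every such omission, so whether the calls not kept were spread along chromosomes by length, as reads from genomic DNA or unspliced RNA might be, is not decided; the fit also assumes that the numbers count all calls made.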
